A study of Rattus norvegicus with 12 samples.

How the data were processed

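Gene expression was measured in primary rat hepatocytes with 1-colour Agilent whole genome arrays, 3 arrays per group in 4 groups. Per the labels, each rat gave freshly isolated cells and nanopillar, sandwich and monolayer cultures taken 95 hours after seeding, and groups and rat numbers were taken from the labels. Per the file headers, Agilent Feature Extraction 10.5.1.1 turned each scan into a background-subtracted, detrended signal in intensity units, with no step between arrays. That signal was the starting point. The authors also deposited a value table in log2 units, centred on each probe's median across arrays. Of its 41090 values per array, 41012 matched a probe of the scanner files, and each array correlated across probes with the equally centred scanner values at r = 0.99986 or more, which settles scale, centring and direction. The array medians of that table ran from -0.36 to 0.45. It served as an alternative only.

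Control spots (1639 per array) and spots marked as outliers by the scanner software (between 82 and 110 per array) were left out. The remaining 43379 spots were averaged to 41012 probes, 263 of which had several spots, and 24 had a missing value on some array. Signals were taken to log2 and each array's 75th percentile was subtracted. Probes well above background on all 3 arrays of at least 1 group were kept, 22603 in number. A gene was represented by its brightest kept probe, which gave 19028 genes, 9900 of them with a gene symbol. Names followed the RefSeq accession for 10735 probes, another accession for 117, a current symbol for 5537 and an older symbol for 3705, and 20918 probes kept the name in the file. Where 2914 genes had several kept probes, these had calls of opposite direction for 59 genes in nanopillar minus monolayer, 4 in nanopillar minus sandwich, 39 in sandwich minus monolayer, 127 in monolayer, 70 in sandwich and 66 in nanopillar minus fresh.

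A linear model with 4 groups was fitted to each gene with lmFit and eBayes of limma 3.58.1 under R 4.3.3, with 8 residual and 2.34 prior degrees of freedom. The 6 differences between groups and the test for any difference were adjusted by the Benjamini-Hochberg method, each over all genes tested, and genes passed at an adjusted p of 0.05. Every adjusted p of a gene is two-sided and comes from this model. A gene not well above background on any array of the dimmer group has a bound only. It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the lowest signal among probes well above background or the gene's own signal, whichever was higher. The distance from fresh cells is the root mean square log2 difference from the mean fresh array, and groups were compared by two-sided exact permutation.

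The 38 lists (31 of gene functions and 7 of markers of other cells) held 1032 tested members, 106 of them in more than 1 list. They were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a contrast. Square brackets beside a list's median hold the median on single slides, and, where it differs, the median with dim genes at their bound. Genes of a list are not independent of each other, which the preset correlation allows for only in small part. The p with an estimated correlation therefore stands beside each call.

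Rat and slide were tested as blocks. Residuals of arrays of the same rat correlated with a mean r of 0.159 for 12 pairs on the same slide and 0.053 for 6 pairs on different slides, against -0.075 for 32 pairs that shared neither and 0.038 for 4 that shared the slide only. The values reported leave rat and slide out of the model, and the count of each contrast with rat as a block stands beside it. Slide 1 held nanopillar 1 and 2, sandwich 1 and fresh 1. Slide 2 held monolayer 1 and 2, sandwich 2 and fresh 2, and slide 3 the third array of each group. Values within slides are therefore single arrays or means of 2.

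The comparisons, the threshold, the lists, the processing and its alternatives were chosen before the data were examined. So was the rule for named genes. It took the 10 largest differences per direction between cultures among genes that passed, had a symbol and had arrays that did not overlap. It took the 10 per direction that passed in all 3 cultures against fresh cells with the largest smallest difference. It also took up to 4 members that passed of each described list, or 2 where none passed, and 20 genes of hepatocyte function and identity in every contrast. Not every gene under the rule and not every list in every contrast is described. Which ones are was decided for length after their values and their stability under the alternatives had been seen, so the share of described results that kept their calls is not that of all results. Each of the 38 lists is given for at least 1 contrast. A few genes under the rule are left out because they are withheld.

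The alternatives were a normexp background with an offset of 50, quantile, median and other 75th percentile scaling, the deposited value table, no filter and a stricter one, the mean of a gene's probes and every probe alone, rat or slide as a block, fits of 2 groups, a trended and robust spread, a test against a fold of 1.5, and each array or rat left out. For lists, an estimated correlation and fry were added. In data simulated on the arrays' own spread, 70 of 100 genes changed 2-fold and 94 of 100 changed 4-fold were found, with 6 false calls (3.53% of calls) and 0 calls where nothing had been changed. A list shifted by 0.5 was called there and no other list was. The simulated noise was independent between genes and held no rat or slide effect. The simulation therefore cannot show how calls fare where genes move together.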

Results

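Gene expression was measured in primary hepatocytes of 3 rats, each as freshly isolated cells and after 95 hours in 3 kinds of culture, on 12 Agilent 1-colour arrays (n = 3 per group, 1 array per rat and condition). A monolayer culture spreads the cells on a flat surface, a sandwich culture holds them between layers of extracellular matrix, and a nanopillar plate carries a surface moulded into pillars far smaller than a cell. The arrays were hybridised on 3 slides of 4 arrays each: monolayer cells were absent from slide 1 and nanopillar cells from slide 2, while sandwich and fresh cells were on every slide. Between 46.3% and 56.5% of the 41012 probes lay well above background, the lowest shares on the 3 fresh arrays, and the 75th percentile of the signal ran from 80.1 to 282.9 intensity units. No spot was saturated. Replicates of 1 group correlated across genes with r between 0.9878 and 0.9949, where genes are not independent replicates. The number of arrays limits the precision of every value. Log2 differences are given with their standard error (SE), and a fold is given as "at least" where a gene was not above background on any array of the lower group.

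The first question, which the 4 conditions pose, was how far each culture had moved from fresh hepatocytes. Over the 19028 genes tested, the root mean square log2 difference from the mean fresh array was 1.98 ± 0.037 (SD, n = 3) in monolayer, 1.43 ± 0.033 in sandwich and 1.29 ± 0.020 in nanopillar cells, against 0.419 ± 0.027 for a fresh array set against the other 2. Monolayer exceeded nanopillar by 0.685 and sandwich by 0.547, and sandwich exceeded nanopillar by 0.138. In each of these 3 pairs no array of 1 group overlapped with the other, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Of the 10025 genes that differed both between monolayer and fresh cells and between nanopillar and monolayer cells, 9156 (91.3%) had a nanopillar mean nearer to fresh than the monolayer mean, and for sandwich cells this held for 7542 of 8354 (90.3%). Among 2068 genes that differed between sandwich and fresh and between nanopillar and sandwich cells, the nanopillar mean lay nearer to fresh for 1795 (86.8%). These shares compare group means that enter both tests, so they are descriptive. The test for any difference among the 4 groups passed for 15781 genes (82.9%). The first principal component (67% of the variance) ordered the groups from monolayer through sandwich and nanopillar to fresh, and the second (21.5%) set sandwich and nanopillar cells apart from the other 2 groups.

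**Figure D1:**
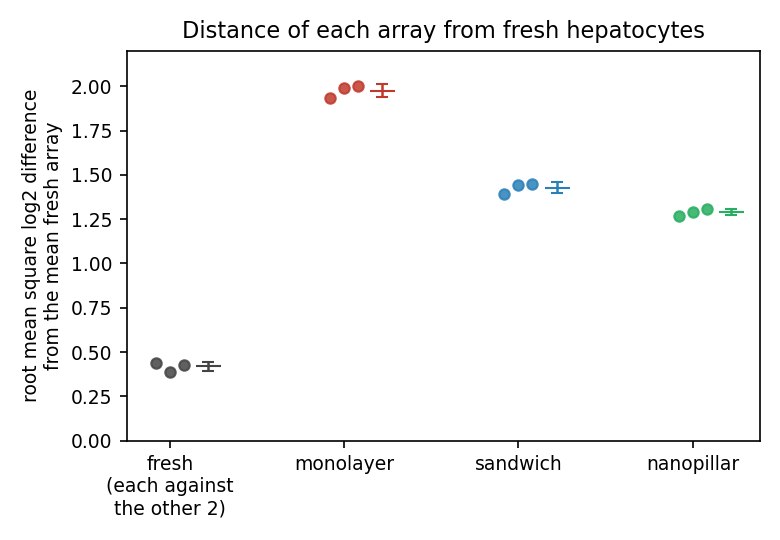
Root mean square log2 difference of each array from the mean fresh array, over all genes tested. Points are arrays, and the bar beside them is the mean with its SD (n = 3). Each fresh array is set against the mean of the other 2 and lies near 0.419, nanopillar arrays near 1.29, sandwich arrays near 1.43 and monolayer arrays near 1.98.

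**Figure D2:**
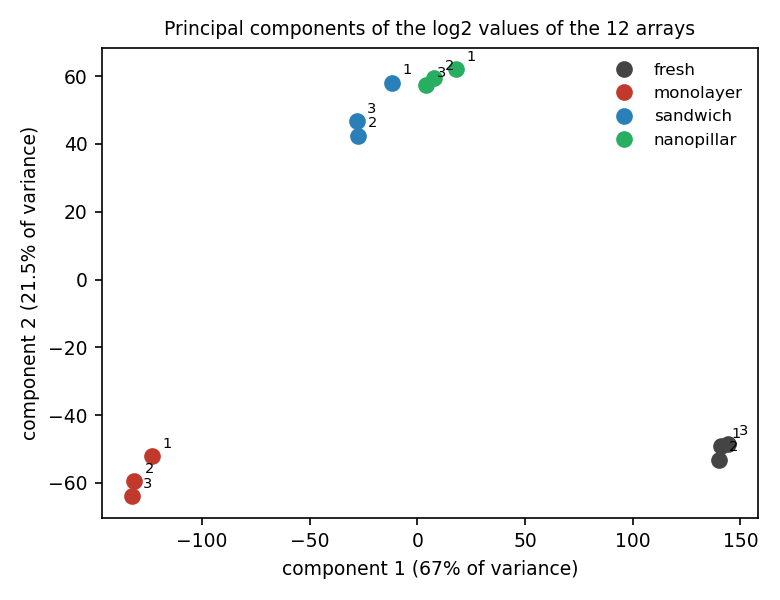
Scores of the 12 arrays on the first 2 principal components of the log2 values, with the replicate number beside each point. Component 1 holds 67% and component 2 holds 21.5% of the variance, and the arrays of each group lie together.

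Nanopillar against monolayer cells compared the pillar plate with the flat culture, whose media the labels do not give. Apart from Abcb1b and Slco1b2, the genes named in this paragraph were higher in nanopillar cells. The cytochrome Cyp3a2 was 535-fold higher (log2 9.07 ± 0.33 SE, n = 3 per group, adjusted p = 2.58e-08), and Slc10a1, which takes bile acids up from the blood, 146-fold higher (log2 7.19 ± 0.24, adjusted p = 1.85e-08). Albumin (Alb) differed less, at 2.31-fold (log2 1.21 ± 0.23, adjusted p = 0.00105). The liver regulators Hnf4a and Cebpa were 5.33-fold and 4.49-fold higher, and the xenobiotic receptor gene Nr1i3 at least 75.8-fold higher. Cyp2c11 was 9.22-fold, Cyp1a2 3.5-fold and Cyp2c12 at least 88.6-fold higher in nanopillar cells. The bile acid enzymes Cyp7a1, the rate-limiting one of the classic pathway, and Cyp8b1 were at least 22.1-fold and at least 106-fold higher. The sulfotransferase Sult2a6 was 158-fold higher, and Sult2a2, above background on 2 of 3 monolayer arrays, was higher by 7.95 on the log2 scale. Among transporters, Slco1a4 was 112-fold higher, the bile salt export pump Abcb11 10.2-fold and Abcc2 2.72-fold, whereas the drug efflux pump Abcb1b was 16.4-fold lower. Slco1b2 gave -0.074 ± 0.15 and did not pass (adjusted p = 0.696). Apart from Slco1b2, each gene named here had an adjusted p of 0.00105 or less.

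Counted by the lists fixed beforehand (where a count adjusted over the list alone differed from that over all genes, it stands beside it), 43 of 49 measured cytochrome P450 and other phase I genes were higher, 2 lower and 4 did not pass. The median was 2.24 [2.70 on slide 3], with adjusted p = 1.49e-11 and adjusted p = 0.0576 with an estimated correlation. Of the phase II conjugating enzymes 38 of 40 were higher and 0 lower (39 higher and 0 lower adjusted over the list alone). The median was 2.33 [2.30 with dim genes at their bound, 2.64 on slide 3], with adjusted p = 9.76e-14 and adjusted p = 0.0646 with an estimated correlation. Sinusoidal uptake transporters showed 19 of 22 higher and 1 lower. The median was 1.41 [1.5 on slide 3], with adjusted p = 2.27e-05 and adjusted p = 0.0783 with an estimated correlation. For canalicular transporters it was 12 of 19 higher and 3 lower, median 0.76 [0.68 on slide 3], adjusted p = 0.023, adjusted p = 0.217 with an estimated correlation, a call that ended with a normexp background (0.67) and in a fit of these 2 groups alone (0.76). Liver transcription factors had 26 of 39 higher and 4 lower. The median was 1.29 [1.16 with dim genes at their bound, 1.17 on slide 3], with adjusted p = 2.87e-05 and adjusted p = 0.0648 with an estimated correlation. Genes of secreted plasma proteins, among them heparin cofactor II (Serpind1, 101-fold higher), were higher for 73 of 80 and lower for 2. The median was 1.75 [1.84 on slide 3], with adjusted p = 5.29e-18 and adjusted p = 0.0646 with an estimated correlation. Bile acid synthesis genes were higher for 18 of 18. The median was 3.20 [3.20 on slide 3], with adjusted p = 7.72e-10 and adjusted p = 0.0576 with an estimated correlation. Pericentral genes, those of hepatocytes near the central vein, were higher for 12 of 21 and lower for 1, median 1.16 [1.07 on slide 3], adjusted p = 0.00499, adjusted p = 0.0646 with an estimated correlation, and the call ended among probes above background on all 12 arrays (1.11). Periportal genes were higher for 20 of 26 and lower for 3 (21 higher and 3 lower adjusted over the list alone). The median was 1.39 [1.35 on slide 3], with adjusted p = 2.87e-05 and adjusted p = 0.0576 with an estimated correlation.

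Most metabolic genes listed were higher too. G6pc1, which releases free glucose, was 290-fold higher in nanopillar cells, Cps1 of the urea cycle 21.8-fold, the fatty acid binding protein Fabp1 31.3-fold and the lipogenic Thrsp 51.8-fold higher, with log2 SEs of 0.21 to 0.37 and adjusted p of 8.57e-08 or less. In the urea cycle and amino acid catabolism list 52 of 57 genes were higher and 1 lower (54 higher and 1 lower adjusted over the list alone). The median was 1.98 [2.01 on slide 3], with adjusted p = 7.26e-16 and adjusted p = 0.0576 with an estimated correlation. Gluconeogenesis, glycogen and fructose metabolism had 23 of 28 higher and 1 lower. The median was 2.73 [2.83 on slide 3], with adjusted p = 3.27e-09 and adjusted p = 0.0576 with an estimated correlation. Fatty acid oxidation and ketogenesis had 32 of 40 higher and 5 lower. The median was 1.38 [1.49 on slide 3], with adjusted p = 5.79e-07 and adjusted p = 0.115 with an estimated correlation. Fatty acid and triglyceride synthesis showed 24 of 28 higher and 1 lower. The median was 2.05 [2.12 on slide 3], with adjusted p = 6.8e-08 and adjusted p = 0.0576 with an estimated correlation. Cholesterol synthesis and uptake genes were higher for 26 of 27. The median was 1.83 [1.87 on slide 3], with adjusted p = 4.38e-11 and adjusted p = 0.0853 with an estimated correlation. All 45 measured genes of the mitochondrial respiratory chain were higher. The median was 0.77 [0.84 on slide 3], with adjusted p = 2.77e-11 and adjusted p = 0.0996 with an estimated correlation. Of the unfolded protein response genes 18 of 32 were higher and 5 lower, median 0.48 [0.64 on slide 3], adjusted p = 0.0257, adjusted p = 0.361 with an estimated correlation, and this call ended with a normexp background (0.37) and with quantile normalization (0.37).

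Some actin cytoskeleton, extracellular matrix and chemokine genes were far lower in nanopillar than in monolayer cells. The smooth muscle protein transgelin (Tagln) was 860-fold lower (log2 -9.75 ± 0.38 SE, n = 3 per group, adjusted p = 3.31e-08), skeletal actin (Acta1) 274-fold, Ankrd1 at least 487-fold and the monocyte chemokine Ccl2 at least 466-fold lower (adjusted p = 1.67e-09). Ccn2, a target of the mechanosensitive regulator YAP, was 13.6-fold lower, the sarcomere genes Nexn and Mybpc3 at least 108-fold and at least 86-fold, the neuropeptide gene Calcb at least 249-fold, the collagen crosslinker Lox 126-fold, cyclin D1 (Ccnd1) 22.9-fold, Cks2 8.26-fold and the early response gene Fosl1 13.3-fold lower. Nppb, Cxcl2 and Loxl2, each above background on 1 of 3 nanopillar arrays, were lower by log2 differences of -8.61, -6.72 and -6.20. The biliary genes Krt7 and Sox9 were at least 58.2-fold and at least 55.1-fold lower. Each gene named so far in this paragraph had an adjusted p of 6.08e-06 or less. Connexin 32 (Gjb1) was 6.2-fold higher and alpha-fetoprotein (Afp) 2.11-fold higher (adjusted p = 0.000256). E-cadherin (Cdh1, -0.14 ± 0.16) and vimentin (Vim, -0.78 ± 0.44) did not pass, at adjusted p = 0.491 and 0.141, though with a normexp background Vim passed.

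Of the actin cytoskeleton list 50 of 57 genes were lower and 2 higher. The median was -1.58 [-1.68 on slide 3], with adjusted p = 6.54e-17 (0.0576 with an estimated correlation). YAP and TEAD targets were lower for 14 of 21 and higher for 3 (3 higher and 15 lower adjusted over the list alone). The median was -1.33 [-1.31 on slide 3], with adjusted p = 0.000187 (0.0646 with an estimated correlation). The epithelial to mesenchymal transition list had 18 of 30 lower and 3 higher. The median was -1.40 [-1.28 with dim genes at their bound, -1.58 on slide 3], with adjusted p = 1.19e-05 (0.0576 with an estimated correlation). Extracellular matrix and integrin genes were lower for 32 of 48 and higher for 7 (8 higher and 33 lower adjusted over the list alone). The median was -2.10 [-1.84 with dim genes at their bound, -1.71 on slide 3], with adjusted p = 8.71e-07 and adjusted p = 0.0576 with an estimated correlation. Immediate early genes were lower for 27 of 40 and higher for 7. The median was -0.92 [-0.56 on slide 3], with adjusted p = 0.000178 (0.299 with an estimated correlation). In the cell cycle list 26 of 53 were lower and 6 higher, median -0.68 [-0.64 with dim genes at their bound, -0.50 on slide 3], adjusted p = 0.000564 (0.361 with an estimated correlation), and with a normexp background its median turned to 0.014. Inflammatory mediators had 19 lower and 12 higher of 36, median -0.82 [-0.46 with dim genes at their bound, -0.84 on slide 3], adjusted p = 0.0457, adjusted p = 0.375 with an estimated correlation, but the median turned to 0.022 with a normexp background and to 0.42 without the filter, and the call ended with quantile normalization (-0.88), median scaling (-0.90) and 3 other settings. Cell junction and polarity genes went both ways, 11 higher and 19 lower of 49 (11 higher and 18 lower adjusted over the list alone), and did not pass, median -0.15 [0.047 on slide 3], adjusted p = 0.114, adjusted p = 0.444 with an estimated correlation, but passed without the filter (-0.15), with every probe on its own (-0.21), by the mixed test of fry and without rat 3 (-0.23, adjusted p between 3.44e-10 and 0.444 over its alternatives). Markers of cholangiocytes, the bile duct cells, were lower for 9 of 15 and higher for 1, median -1.34 [-0.76 with dim genes at their bound, -1.82 on slide 3], adjusted p = 0.00409 (0.0576 with an estimated correlation), with a median of 0.030 without the filter. Mesothelial and smooth muscle markers were lower for 8 of 12 and higher for 2, median -1.72 [-1.52 with dim genes at their bound, -1.85 on slide 3], adjusted p = 0.0135, adjusted p = 0.0646 with an estimated correlation, and 0.37 among probes above background on all 12 arrays. Of 3 measured erythroid markers 2 were higher, and the list did not pass, median 1.40 [2.13 on slide 3], adjusted p = 0.287, adjusted p = 0.461 with an estimated correlation, and the median was 0.078 without monolayer 1.

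In total 11789 of 19028 genes (62%) passed at an adjusted p of 0.05, 6568 higher and 5221 lower in nanopillar cells, 5296 of them by at least 2-fold (2671 with a normexp background). The 3 arrays of each group did not overlap for 11452 of the called genes and for 13223 of all genes, where chance gives 10%. With rat as a block 12237 genes passed, and with slide as a block 10613. The split depended on the scaling: with the 75th percentile taken over probes above background on all arrays, 44.4% of the called genes were higher in place of 55.7%, and the median of all genes moved from 0.094 to -0.063. Camera passed 26 of the 38 lists, all with the same sign with slide as a block and on slide 3, and none of them with an estimated correlation.

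Nanopillar against sandwich cells compared the culture types nearer to fresh cells. Fewer genes passed than in the other contrasts. The metallothionein Mt1 was 22.9-fold higher in nanopillar cells (log2 4.52 ± 0.32 SE, n = 3 per group, adjusted p = 0.00028), and the zinc exporter Slc30a2 10.2-fold higher (log2 3.35 ± 0.33, adjusted p = 0.000524). The complement inhibitor subunit C4bpb was 13.7-fold higher (log2 3.77 ± 0.21, adjusted p = 7.34e-05), Serpind1 7.35-fold, Itih4 3.8-fold, the fibrinogen-like Fgl1 4.24-fold and Aspg 14.3-fold higher. Cyp3a2 was 8.36-fold and Cyp2c7 6.98-fold higher, and Slc10a1 5.47-fold, while Cyp2c11 was 4-fold lower (adjusted p = 0.0175). Another Cyp2c7 probe gave 1.17 and did not pass (adjusted p = 0.093). Cyp2c12 was higher by 7.31 ± 0.76 on the log2 scale, with 1 of 3 sandwich arrays above background, by 3.50 with a normexp background, and did not pass without rat 2 (adjusted p = 0.0533). The bile salt export pump Abcb11 was 1.54-fold higher (adjusted p = 0.0234). Alb (0.088 ± 0.23), Hnf4a (0.064 ± 0.12) and Abcc2 (0.15 ± 0.23) did not pass, at adjusted p = 0.83, 0.759 and 0.702, and the sign of Alb turned with quantile normalization (-0.009). Cyp7a1 gave 1.34 ± 0.41 (adjusted p = 0.0587) and passed with rat as a block, with quantile normalization, with a trended and robust spread and without sandwich 1 (adjusted p between 0.0114 and 1 over its alternatives).

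Oxidative stress genes and lipid genes formed a further part. Gstp1 was 11.2-fold, Akr1b8 12.4-fold and heme oxygenase (Hmox1) 4.69-fold higher in nanopillar cells. The lipase gene Pnpla5 was 11.4-fold, the desaturases Fads1 and Fads2 2.86-fold and 3.46-fold, and lanosterol synthase (Lss) 2.14-fold higher. Nr0b2, a repressor in bile acid signalling, was 5.73-fold higher. Angptl4 and Cyp4a1, both known targets of the fatty acid receptor PPAR alpha, were 3.62-fold and 2.15-fold lower. Other genes were lower in nanopillar cells: Vim by 3.45-fold (adjusted p = 0.0252), Ccn2 4.55-fold, Anxa8 7.2-fold, Sox4 5.78-fold, Timp2 5.09-fold and the cell surface gene Cd24 4.4-fold. The ileal bile acid carrier Slc10a2 was 3.72-fold lower. Cav1, Ptpn14 and Lhfpl6, above background on only some nanopillar arrays, were lower by log2 differences of -2.67, -1.76 and -3.83. Each SE of these log2 differences lay between 0.14 and 0.57, and each adjusted p was 0.0252 or less.

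By list, plasma protein genes were higher for 39 of 80 and lower for none (59 higher and 1 lower adjusted over the list alone). The median was 0.54 [0.49 and 0.60 on slides 1 and 3], with adjusted p = 3.81e-21 and adjusted p = 0.19 with an estimated correlation. Acute phase genes were higher for 11 of 33 (18 higher and 0 lower adjusted over the list alone). The median was 0.57 [0.66 and 0.56 on slides 1 and 3], with adjusted p = 5.09e-08 and adjusted p = 0.19 with an estimated correlation. Cholesterol synthesis had 19 of 27 higher (22 higher and 0 lower adjusted over the list alone), median 0.65 [0.66 and 0.64 on slides 1 and 3], adjusted p = 5.85e-14, adjusted p = 0.19 with an estimated correlation. Fatty acid synthesis had 13 of 28 (17 higher and 0 lower adjusted over the list alone). The median was 0.67 [0.67 and 0.55 on slides 1 and 3], with adjusted p = 1.25e-07 and adjusted p = 0.19 with an estimated correlation. The Nrf2 target list had 17 of 33 higher and 2 lower (19 higher and 3 lower adjusted over the list alone). The median was 0.49 [0.38 and 0.63 on slides 1 and 3], with adjusted p = 1.49e-07 and adjusted p = 0.19 with an estimated correlation. Phase I genes were higher for 18 and lower for 5 of 49 (22 higher and 8 lower adjusted over the list alone). The median was 0.50 [0.36 and 0.55 on slides 1 and 3], with adjusted p = 0.000451 and adjusted p = 0.302 with an estimated correlation. Of the phase II genes 8 of 40 were higher and 1 lower (21 higher and 1 lower adjusted over the list alone). The median was 0.46 [0.40 with dim genes at their bound, 0.31 and 0.53 on slides 1 and 3], with adjusted p = 4.64e-06 and adjusted p = 0.302 with an estimated correlation. Bile acid synthesis genes were higher for 8 of 18 (10 higher and 0 lower adjusted over the list alone). The median was 0.68 [0.40 and 0.68 on slides 1 and 3], with adjusted p = 0.000182 and adjusted p = 0.259 with an estimated correlation. Fatty acid oxidation genes were lower for 12 and higher for 3 of 40 (7 higher and 15 lower adjusted over the list alone), with a median of -0.27 without rat 3. The median was -0.16 [-0.28 and -0.077 on slides 1 and 3], with adjusted p = 0.00204 and adjusted p = 0.321 with an estimated correlation. Actin genes were lower for 14 and higher for 2 of 57 (2 higher and 18 lower adjusted over the list alone). The median was -0.25 [-0.15 and -0.26 on slides 1 and 3], with adjusted p = 8.96e-05 and adjusted p = 0.316 with an estimated correlation. YAP and TEAD targets had 6 lower and 3 higher of 21 (3 higher and 9 lower adjusted over the list alone), median -0.48 [-0.43 and -0.55 on slides 1 and 3], adjusted p = 0.000636, adjusted p = 0.19 with an estimated correlation, a call lost among probes above background on all 12 arrays (-0.21). For matrix genes it was 10 lower and 3 higher of 48 (5 higher and 12 lower adjusted over the list alone), median -0.18 [-0.055 and -0.15 on slides 1 and 3], adjusted p = 0.0102, adjusted p = 0.302 with an estimated correlation, and this call was lost there too (-0.092), without nanopillar 2 (-0.17) and without rat 2 (-0.093).

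Marker lists of other liver cells, each tested only in part, did not pass with camera, though all 5 did by the mixed test of fry. Of 31 stellate, 33 macrophage and 34 endothelial markers listed, 13, 13 and 17 were tested. Stellate markers had 4 of 13 higher (5 higher and 1 lower adjusted over the list alone), median 0.16 [0.32 and 0.24 on slides 1 and 3], adjusted p = 0.0859, adjusted p = 0.302 with an estimated correlation, and passed with the mean of a gene's probes, with every probe on its own and without sandwich 2 (0.27), with medians from 0.080 without rat 1 to 0.30 without rat 3. One macrophage marker of 13 was higher, with medians from 0.12 without rat 1 to 0.34 without nanopillar 2. The median was 0.22 [0.21 and 0.38 on slides 1 and 3], with adjusted p = 0.0914 and adjusted p = 0.266 with an estimated correlation. Endothelial markers had 1 higher and 1 lower of 17, median 0.015 [0.29 and -0.30 on slides 1 and 3], adjusted p = 0.799, adjusted p = 0.856 with an estimated correlation, with a median that turned negative under several scalings, filters and left-out arrays (from -0.17 to 0.17 over single libraries left out). Cholangiocyte markers were lower for 4 of 15 (0 higher and 5 lower adjusted over the list alone), median -0.43 [-0.44 and -0.33 on slides 1 and 3], adjusted p = 0.0523, adjusted p = 0.259 with an estimated correlation, and this list passed with slide as a block (-0.41), with a normexp background (-0.004), with the deposited values, with 3 other choices of probes or filter and without nanopillar 1 (-0.29), nanopillar 2 (-0.29), sandwich 2 (-0.47) or rat 2 (-0.47), and the median was -0.17 without rat 3. Of 6 lymphocyte and neutrophil markers 1 was higher and 1 lower, with medians from 0.29 without sandwich 1 to 0.68 without rat 3. The median was 0.43 [0.91 and -0.063 on slides 1 and 3], with adjusted p = 0.153 and adjusted p = 0.302 with an estimated correlation.

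In total 2448 genes (12.9%) passed, 1302 higher and 1146 lower in nanopillar cells, 631 by at least 2-fold (208 with a normexp background). The groups did not overlap for 2424 of these and for 6416 of all genes, where chance gives 10%. With rat as a block 3023 passed, and with slide as a block 2218. This count rested on single libraries more than any other: 522 genes passed without rat 1, 120 without rat 2, 724 without rat 3, 1062 without nanopillar 1, 969 without sandwich 2 and 1154 without sandwich 3. Those of at least 2-fold fell to 366, 118 and 395 without rats 1, 2 and 3, 406 without nanopillar 1 and 418 without sandwich 2. Without rat 2 81 were higher and 39 lower, and without nanopillar 2 736 were lower. Of the 33 genes named above that passed, 26 still passed without rat 1, 16 without rat 2 and 24 without rat 3, and all 33 kept their sign each time. Against a fold of 1.5 it was 23 of them, and without the filter 30. Those that passed without any 1 of the 3 rats were Mt1, Slc30a2, C4bpb, Serpind1, Aspg, Gstp1, Nr0b2, Fads1, Fads2, Angptl4, Fgl1, Anxa8, Slc10a1 and Cyp2c7. Leaving out single arrays kept between 29 and 33 of them, with Abcb11, Vim, Cd24 and Cyp2c11 those lost. With the 75th percentile over probes above background on all arrays, 42.9% of the called genes were higher in place of 53.2%. Camera passed 19 of the 38 lists, all 19 with the same sign with slide as a block and 18 on each slide, the exception being the sinusoidal uptake list on slide 1 (-0.002), and none passed with an estimated correlation.

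Sandwich cells were then set against monolayer cells, with the same 3 monolayer arrays as before. Alb was 2.17-fold higher in sandwich cells (log2 1.12 ± 0.23 SE, n = 3 per group, adjusted p = 0.0022), Hnf4a 5.1-fold higher (log2 2.35 ± 0.12, adjusted p = 2.55e-07) and Cyp3a2 64-fold higher. Cyp2c11 was 36.9-fold, Cyp7a1 at least 8.76-fold, Slc10a1 26.7-fold and Abcb11 6.63-fold higher. G6pc1 was 295-fold, Sult2a6 65.9-fold, the glycine conjugating enzyme Glyat 40-fold, Galnt18 46.3-fold and Slco1a5 at least 12.7-fold higher. Tagln was 965-fold lower, Acta1 240-fold, Ankrd1 303-fold, Ccl2 at least 467-fold and follistatin (Fst) at least 82.3-fold lower, and Nppb, above background on 2 of 3 sandwich arrays, was lower by a log2 difference of -8.44. Gstp1 and Akr1b8 were 14-fold and 12.1-fold lower in sandwich cells. Each of these genes but Alb had an adjusted p of 0.000394 or less, and without rat 2 Alb did not pass (adjusted p = 0.0543, between 0.00014 and 0.103 over its alternatives).

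Phase I genes were higher for 39 and lower for 3 of 49 (39 higher and 4 lower adjusted over the list alone). The median was 2.12 [1.99 and 2.16 on slides 2 and 3], with adjusted p = 1.65e-11 and adjusted p = 0.0599 with an estimated correlation. Plasma protein genes were higher for 68 and lower for 4 of 80 (70 higher and 6 lower adjusted over the list alone). The median was 1.16 [1.19 and 1.16 on slides 2 and 3], with adjusted p = 4.23e-14 and adjusted p = 0.0854 with an estimated correlation. All 18 measured bile acid synthesis genes were higher, median 2.47 [2.44 and 2.35 on slides 2 and 3], adjusted p = 2.51e-10, adjusted p = 0.0599 with an estimated correlation, and fatty acid oxidation genes were higher for 35 and lower for 2 of 40 (36 higher and 2 lower adjusted over the list alone). The median was 1.36 [1.34 and 1.38 on slides 2 and 3], with adjusted p = 3.01e-12 and adjusted p = 0.0599 with an estimated correlation. Actin cytoskeleton genes were lower for 47 and higher for 1 of 57. The median was -1.34 [-1.39 and -1.43 on slides 2 and 3], with adjusted p = 1.42e-17 and adjusted p = 0.0599 with an estimated correlation. The Nrf2 target list had 16 higher and 7 lower of 33 (16 higher and 8 lower adjusted over the list alone) and did not pass, median 0.32 [0.44 and 0.41 on slides 2 and 3], adjusted p = 0.633, adjusted p = 0.891 with an estimated correlation, with a median of -0.010 when every probe was tested on its own. In total 9649 genes (50.7%) passed, 5545 higher and 4104 lower, 4026 by at least 2-fold (1977 with a normexp background). The groups did not overlap for 9541 of these and for 12225 of all genes, where chance gives 10%. With rat as a block 10311 passed, and with slide as a block 9980. The number lower fell to 2704 without rat 2. With the 75th percentile over probes above background on all arrays, 45.7% of the called genes were higher in place of 57.5%, and the median of all genes moved from 0.081 to -0.046. Camera passed 24 of the 38 lists, with the same sign with slide as a block and on each slide, and none of them with an estimated correlation.

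Each culture was then set against fresh cells, which asks what 95 hours outside the liver changed. The genes named in this paragraph were lower in all 3 cultures. Cyp3a2 was 7620-fold lower in monolayer (log2 -12.90 ± 0.33 SE, n = 3 per group, adjusted p = 2.78e-10), 119-fold in sandwich (log2 -6.90 ± 0.33, adjusted p = 4.08e-08) and 14.2-fold in nanopillar cells (log2 -3.83 ± 0.33, adjusted p = 3.91e-06). In the same order, Slc10a1 was 1130-fold, 42.2-fold and 7.7-fold lower, Cps1 42.3-fold, 1.92-fold and 1.94-fold, Cyp2c11 512-fold, 13.9-fold and 55.6-fold, and Cebpa 26.4-fold, 7.59-fold and 5.88-fold lower. In the same order, the gluconeogenic Pck1 was lower by 1020-fold, 1100-fold and 1020-fold, Slco1b2 by 62.2-fold, 77.6-fold and 65.5-fold, and Cyp1a2 by 1220-fold, 295-fold and 348-fold. Cyp2e1 fell by log2 differences of -13.69, -10.37 and -9.88, with 2 of 3 monolayer arrays above background.

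Alb was 4.16-fold, 1.92-fold and 1.81-fold lower in monolayer, sandwich and nanopillar cells (adjusted p = 1.25e-05, 0.00473 and 0.00921), but not past the threshold in sandwich (-0.018) and nanopillar cells (-0.026) with quantile normalization, nor in nanopillar cells without rat 2 (adjusted p = 0.0743, between 0.00241 and 0.859 over its alternatives). Abcb11 was 10.4-fold lower in monolayer and 1.57-fold lower in sandwich cells, the latter not without rat 2 (adjusted p = 0.0831, between 0.000988 and 0.737 over its alternatives), and gave -0.03 ± 0.15 in nanopillar cells (adjusted p = 0.874), where normexp, quantile, median and restricted 75th percentile scaling turned the sign. Hnf4a was 5.49-fold lower in monolayer cells and gave -0.11 ± 0.12 in sandwich and -0.042 ± 0.12 in nanopillar cells (adjusted p = 0.468 and 0.787). Its probes disagreed: another Hnf4a probe gave -0.97 and -0.72, both past the threshold, and a normexp background gave 0.066 and 0.11. Nr0b2 was 3170-fold lower in sandwich and 552-fold lower in nanopillar cells, and in monolayer cells, with 1 of 3 arrays above background, by a log2 difference of -12.78. The sulfotransferase Sult1c3 was 2400-fold, 577-fold and 441-fold lower, Gstp3 1090-fold, 548-fold and 366-fold, and the urinary protein gene Rup2 3820-fold, 1560-fold and 578-fold lower. The clock genes Dbp and Nr1d1 were lower too, Dbp by 83.2-fold, 30.2-fold and 30.2-fold and Nr1d1 by 29.4-fold, 18.8-fold and 17.4-fold. Kdr, a receptor of endothelial cells, was at least 221-fold lower in monolayer and at least 162-fold lower in nanopillar cells, and in sandwich cells, with 1 of 3 arrays above background, by a log2 difference of -8.44.

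A further set of genes was higher in every culture. In monolayer, sandwich and nanopillar cells Vim was at least 248-fold, at least 497-fold and at least 144-fold higher, Anxa2 1070-fold, 660-fold and 402-fold, the small heat shock gene Cryab 555-fold, 491-fold and 294-fold, the actin binding Tmsb10 232-fold, 241-fold and 177-fold, and Ccn2 1800-fold, 603-fold and 133-fold. Adrenomedullin (Adm) was at least 992-fold higher in monolayer and at least 48.3-fold higher in nanopillar cells, and its bound in sandwich cells was 6.71 on the log2 scale. S100a6 and Abcb1b, each above background on 1 of 3 fresh arrays, were higher by log2 differences of 12.02, 7.84 and 8.19 and of 7.16, 4.07 and 3.13. Cyclin D1 (Ccnd1) was 76.5-fold lower in sandwich and 151-fold lower in nanopillar cells. The cholesterol enzyme Sqle was 7.15-fold and 12.2-fold higher there. Each of these log2 differences passed, with SEs of 0.11 to 0.44 and adjusted p of 9.97e-05 or less.

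By list against fresh cells, plasma protein genes were lower for 80 of 80 in monolayer. The median was -3.43 [-3.47 and -3.49 on slides 2 and 3], with adjusted p = 8.4e-23 and adjusted p = 0.0586 with an estimated correlation. In sandwich cells 78 were lower, median -2.32 [-2.13, -2.36 and -2.29 on slides 1, 2 and 3], adjusted p = 4.47e-25, adjusted p = 0.0965 with an estimated correlation, and in nanopillar cells 76 lower and 1 higher (1 higher and 77 lower adjusted over the list alone). The median was -1.66 [-1.66 and -1.53 on slides 1 and 3], with adjusted p = 1.46e-22 and adjusted p = 0.0904 with an estimated correlation. Phase I genes were lower for 44 of 49 and higher for 4 in monolayer. The median was -3.99 [-3.99 and -4.64 on slides 2 and 3], with adjusted p = 4.24e-12 and adjusted p = 0.0586 with an estimated correlation. For sandwich cells it was 38 lower and 6 higher, median -1.99 [-1.87, -2.07 and -1.98 on slides 1, 2 and 3], adjusted p = 7.37e-09, adjusted p = 0.119 with an estimated correlation, and for nanopillar cells 32 lower and 7 higher. The median was -1.55 [-1.57 and -1.39 on slides 1 and 3], with adjusted p = 1.96e-07 and adjusted p = 0.183 with an estimated correlation. Pericentral genes were lower for 20 of 21 in monolayer (0 higher and 21 lower adjusted over the list alone). The median was -3.18 [-3.02 with dim genes at their bound, -3.45 and -3.03 on slides 2 and 3], with adjusted p = 4.02e-08 and adjusted p = 0.0216 with an estimated correlation. Sandwich cells had 14 lower and 1 higher, median -3.03 [-2.74 with dim genes at their bound, -2.82, -3.25 and -2.69 on slides 1, 2 and 3], adjusted p = 6.13e-06, adjusted p = 0.0628 with an estimated correlation, and nanopillar cells 15 lower and 2 higher. The median was -2.74 [-2.57 with dim genes at their bound, -2.59 and -2.19 on slides 1 and 3], with adjusted p = 2.17e-06 and adjusted p = 0.0485 with an estimated correlation. Actin cytoskeleton genes were higher for 52 of 57 and lower for 3 in monolayer (53 higher and 3 lower adjusted over the list alone). The median was 2.96 [2.88 with dim genes at their bound, 2.94 and 3.00 on slides 2 and 3], with adjusted p = 8.67e-16 and adjusted p = 0.0617 with an estimated correlation. In sandwich cells 40 were higher and 3 lower (41 higher and 3 lower adjusted over the list alone), median 1.30 [1.02 with dim genes at their bound, 0.89, 1.55 and 1.41 on slides 1, 2 and 3], adjusted p = 4.44e-08, adjusted p = 0.188 with an estimated correlation, and in nanopillar cells 35 higher and 5 lower (35 higher and 6 lower adjusted over the list alone). The median was 0.82 [0.80 with dim genes at their bound, 0.74 and 1.03 on slides 1 and 3], with adjusted p = 1.87e-07 and adjusted p = 0.211 with an estimated correlation.

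Cholesterol genes had medians that differed in sign. In monolayer cells 17 of 27 were lower and 4 higher, median -0.82 [-0.67 and -0.97 on slides 2 and 3], adjusted p = 0.0111, adjusted p = 0.48 with an estimated correlation, a call lost with a normexp background (-0.51), without the filter (-0.69) and without rat 3 (-0.61). In sandwich cells 16 were higher and 8 lower (17 higher and 8 lower adjusted over the list alone), and the list did not pass, median 0.54 [0.82, 0.70 and 0.25 on slides 1, 2 and 3], adjusted p = 0.143, adjusted p = 0.658 with an estimated correlation, but passed with a normexp background (0.79), without the filter (0.63) and without rat 3 (0.77). In nanopillar cells 18 were higher and 5 lower. The median was 1.13 [1.36 and 0.91 on slides 1 and 3], with adjusted p = 0.000273 and adjusted p = 0.407 with an estimated correlation. Cell cycle genes were lower for 30 of 53 and higher for 12 in monolayer, median -0.90 [-1.20 and -0.83 on slides 2 and 3], adjusted p = 0.0893, adjusted p = 0.619 with an estimated correlation, and this list passed with quantile normalization (-0.87), without fresh 1 (-1.18) and without rat 1 (-1.07). In sandwich cells 34 were lower and 6 higher, median -1.18 [-1.10 with dim genes at their bound, -0.95, -1.26 and -1.22 on slides 1, 2 and 3], adjusted p = 3.4e-05, adjusted p = 0.32 with an estimated correlation, and in nanopillar cells 38 lower and 3 higher (3 higher and 39 lower adjusted over the list alone). The median was -1.39 [-1.23 and -1.13 on slides 1 and 3], with adjusted p = 2.14e-07 and adjusted p = 0.211 with an estimated correlation. Clock genes were lower for 11 of 20 in monolayer and higher for 5. The median was -0.41 [-0.54 and -0.22 on slides 2 and 3], with adjusted p = 0.119 and adjusted p = 0.399 with an estimated correlation. They were lower for 13 and higher for 3 in sandwich (3 higher and 14 lower adjusted over the list alone), median -0.86 [-1.24, -0.61 and -0.67 on slides 1, 2 and 3], adjusted p = 0.00301, adjusted p = 0.181 with an estimated correlation, and lower for 13 and higher for 3 in nanopillar cells. The median was -0.99 [-1.10 and -0.73 on slides 1 and 3], with adjusted p = 0.00279 and adjusted p = 0.205 with an estimated correlation. The labels give no hour of collection.

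Of the marker lists, 2 are given against fresh cells. Endothelial markers were lower for 12 of 17 in monolayer and higher for 4, median -2.35 [-2.20 and -2.76 on slides 2 and 3], adjusted p = 0.0393, adjusted p = 0.231 with an estimated correlation, a call lost with a normexp background (-1.67), with every probe on its own (-2.30), without rat 1 (-2.46) and without rat 3 (-2.11). They were lower for 14 in sandwich and higher for 3, median -2.15 [-1.93 with dim genes at their bound, -2.26, -1.98 and -2.36 on slides 1, 2 and 3], adjusted p = 0.000159, adjusted p = 0.101 with an estimated correlation, and lower for 14 in nanopillar cells and higher for 1. The median was -2.19 [-2.42 and -2.32 on slides 1 and 3], with adjusted p = 1.59e-05 and adjusted p = 0.0904 with an estimated correlation. In all 3 cultures the endothelial call was lost among probes above background on all 12 arrays (-1.28, -1.24 and -1.16). Macrophage markers were lower for 10 of 13 in monolayer and higher for 3, median -1.34 [-1.27 and -1.51 on slides 2 and 3], adjusted p = 0.0753, adjusted p = 0.143 with an estimated correlation, and passed with quantile normalization (-1.25), the restricted 75th percentile (-1.14) and every probe on its own. In sandwich cells 10 were lower and 1 higher (3 higher and 10 lower adjusted over the list alone), median -1.10 [-0.93, -1.0 and -1.53 on slides 1, 2 and 3], adjusted p = 0.0299, adjusted p = 0.126 with an estimated correlation, a call lost without rat 1 (-0.94) and among probes above background on all 12 arrays (-0.76). Nanopillar cells had 9 lower and 3 higher, median -1.03 [-0.68 and -1.34 on slides 1 and 3], adjusted p = 0.0753, adjusted p = 0.205 with an estimated correlation, and this passed without rat 3 (-0.88) and with every probe on its own, and the median was -0.67 without rat 2.

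In monolayer cells the glycolysis isoforms found mainly outside the adult liver were higher for 11 of 17 and lower for 3, median 1.32 [1.01 and 1.79 on slides 2 and 3], adjusted p = 0.00681, adjusted p = 0.317 with an estimated correlation, a call lost among probes above background on all 12 arrays (0.45). The other 3 lists did not pass. Fetal liver genes were higher for 13 and lower for 7 of 20, median 2.27 [1.09 with dim genes at their bound, 2.01 and 2.05 on slides 2 and 3], adjusted p = 0.0753, adjusted p = 0.137 with an estimated correlation, with a negative median without the filter (-0.76) and among probes above background on all 12 arrays (-0.46). Basolateral efflux transporters were higher for 5 and lower for 3 of 8, median 1.58 [1.45 and 1.59 on slides 2 and 3], adjusted p = 0.453, adjusted p = 0.594 with an estimated correlation, and -0.084 among those probes. Hypoxia genes were higher for 13 and lower for 10 of 28, median 0.21 [0.057 and 0.20 on slides 2 and 3], adjusted p = 0.536, adjusted p = 0.838 with an estimated correlation, and their median turned negative in 4 settings, among them the mean of a gene's probes (-0.047), and was 0.43 without rat 1.

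**Figure D3:**
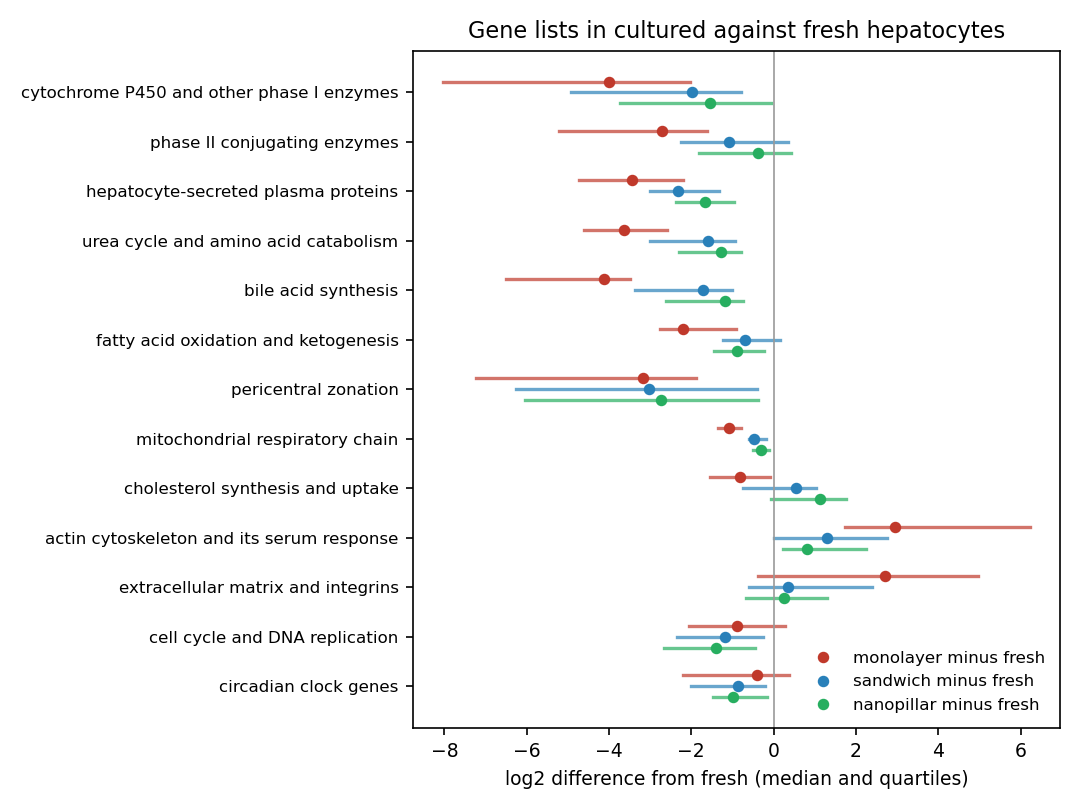
Log2 difference of each culture from fresh cells for 13 of the gene lists. The dot is the median over the measured genes of a list and the line joins their quartiles. Plasma protein, phase I and pericentral genes lie below 0 in all 3 cultures and actin cytoskeleton genes above 0, while the cholesterol list has medians of -0.82 in monolayer, 0.54 in sandwich and 1.13 in nanopillar cells.

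**Figure D4:**
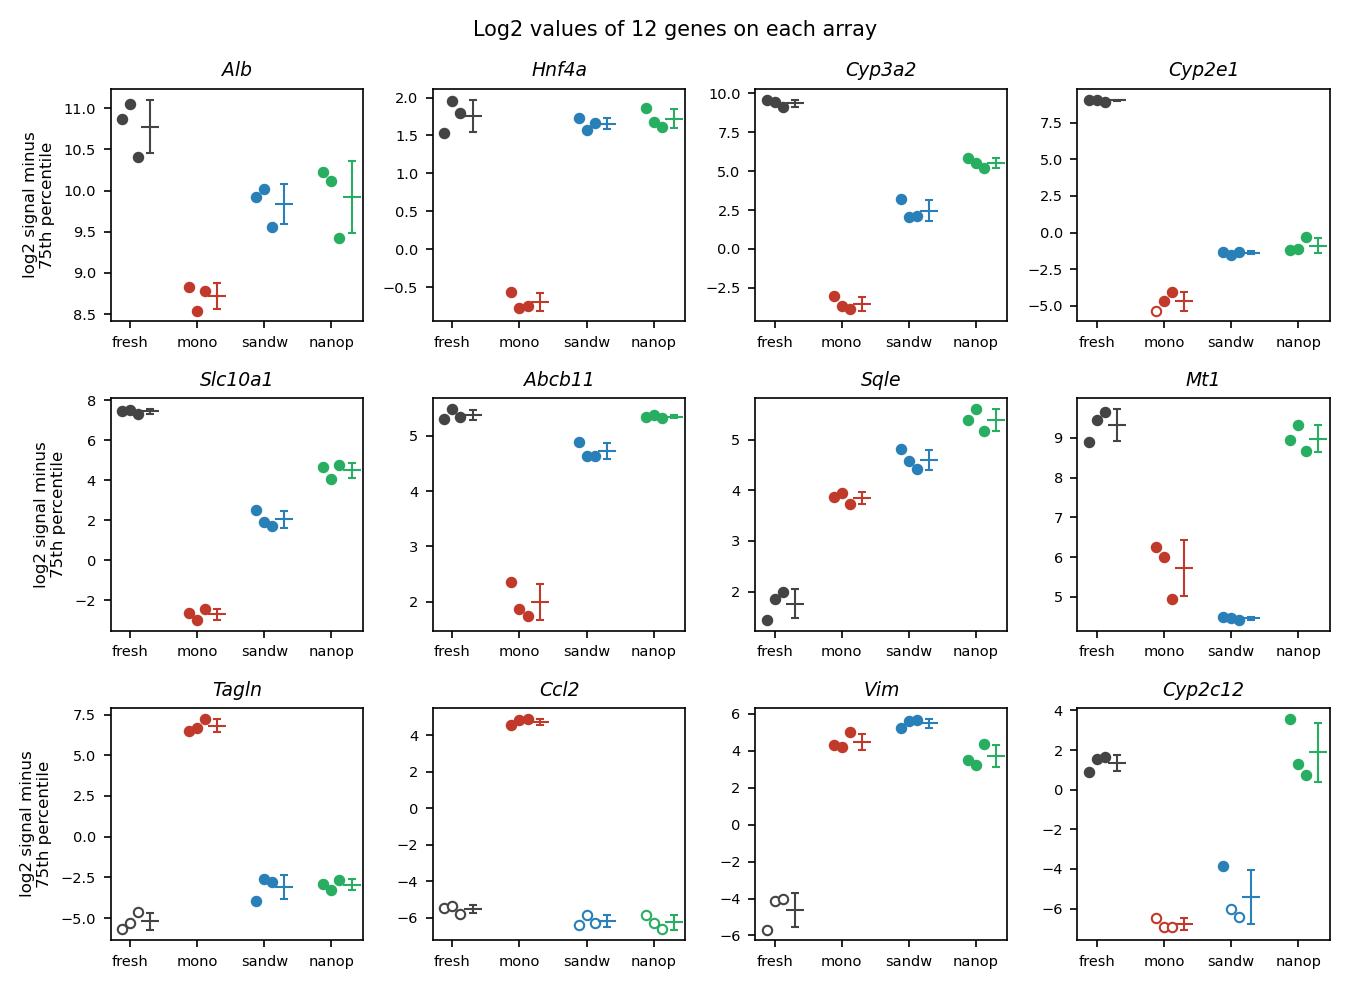
Log2 signal, relative to the 75th percentile of its array, of 12 genes on each array of fresh, monolayer (mono), sandwich (sandw) and nanopillar (nanop) cells. Points are arrays, open where the probe was not well above background, and the bar is the mean with its SD (n = 3). Tagln and Ccl2 are high on the monolayer arrays, and Mt1 and Cyp2c12 on the fresh and nanopillar arrays.

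Against fresh cells 14290 genes (75.1%) passed in monolayer (6826 higher, 7464 lower, 8424 by at least 2-fold), 11867 (62.4%) in sandwich (5886 higher, 5981 lower, 5306 by at least 2-fold) and 10961 (57.6%) in nanopillar cells (5483 higher, 5478 lower, 4459 by at least 2-fold). A normexp background left 5390, 2680 and 2104 of at least 2-fold. The groups did not overlap for 15002, 12695 and 11696 of all genes, where chance gives 10%. With rat as a block 14575, 12383 and 11483 passed, and with slide as a block 14505, 12643 and 11404. In the same direction in all 3 cultures, 8040 genes passed, 3952 higher and 4088 lower, where 3 independent lists of these sizes would share 1283.9. The 3 contrasts use the same fresh arrays, so shared calls are not independent, and how far this raises their number was not measured. Of these genes 1620 were higher and 1622 lower by at least 2-fold in every culture. With a normexp background the share of called genes that were higher fell to 35.1% in monolayer, 36.4% in sandwich and 38% in nanopillar cells, from 47.8%, 49.6% and 50%, and the median of all genes moved from -0.057, -0.026 and -0.017 to -0.35, -0.21 and -0.18. With the 75th percentile over probes above background on all arrays, the monolayer median moved to 0.15. Under normexp, 975 of the 12330 monolayer genes still called had the opposite direction, 298 of 9418 in sandwich and 114 of 8264 in nanopillar cells. Camera passed 22, 20 and 19 of the 38 lists, all with the same sign within each slide, and the pericentral list in monolayer and nanopillar cells was the one that passed with an estimated correlation.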

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

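None of the alternatives below was chosen after the data had been seen. Scan date as a block was not run, because all arrays carry 1 scan date. Without a left-out library, the 186 gene results were compared with 2416 alternative values. Of these, 2376 kept direction and side of the threshold, 24 lost their call, 8 gained one and 8 turned direction. For the 87 list results it was 1148 of 1305 kept, 90 lost, 48 gained and 19 turned. Of counts and distances 346 of 395 were kept, and 49, all counts, moved by more than 1.5 times. Distances could not change call (permutation p at least 0.1). When 1 array or 1 rat was left out, 1612 of 1674 gene values were kept, 49 lost, 1 gained and 12 turned. Of list values 762 of 783 were kept, 6 lost, 10 gained and 5 turned. Of counts and distances 257 of 282 were kept and 25 moved. The distances from fresh cells kept their direction throughout, between 0.669 and 0.695 for monolayer minus nanopillar, 0.525 and 0.559 for monolayer minus sandwich, and 0.126 and 0.158 for sandwich minus nanopillar when libraries were left out. Signal over background limits what can be seen: between 46.3% and 56.5% of probes lay well above it, and folds against a dim group are lower bounds. Except where a sentence says otherwise, the cause of a change was not tested. In what follows a value after a gene is its log2 difference, a value after a list is its median log2 difference, and a count is that of genes past the threshold.

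Background and scaling changed the following. With a normexp background, direction turned for cell cycle 0.014 and inflammatory 0.022 in nanopillar minus monolayer, Hnf4a 0.066 in sandwich minus fresh and Abcb11 0.24 and Hnf4a 0.11 in nanopillar minus fresh. Calls were lost for canalicular 0.67 and unfolded protein 0.37 in nanopillar minus monolayer and cholesterol -0.51 and endothelial -1.67 in monolayer minus fresh and gained for cholangiocyte -0.004 in nanopillar minus sandwich, fetal 0.42 in monolayer minus fresh and cholesterol 0.79 in sandwich minus fresh. The nanopillar minus sandwich count was 1617, of which 1425 genes were among the 2448. Quantile normalization turned Alb -0.009 in nanopillar minus sandwich and Abcb11 0.15 in nanopillar minus fresh. It ended the calls of inflammatory -0.88 and unfolded protein 0.37 in nanopillar minus monolayer and added cell cycle -0.87 and macrophage -1.25 in monolayer minus fresh. Median scaling turned endothelial -0.021 in nanopillar minus sandwich and Abcb11 0.002 in nanopillar minus fresh and ended the call of inflammatory -0.90 in nanopillar minus monolayer. The 75th percentile over probes above background on all arrays turned endothelial -0.015 in nanopillar minus sandwich and Abcb11 0.016 and Hnf4a 0.005 in nanopillar minus fresh, ended the call of inflammatory -0.97 in nanopillar minus monolayer and added macrophage -1.14 in monolayer minus fresh.

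The choice of probes mattered for lists of dim genes. Restricted to probes above background on all 12 arrays, which leaves fewer genes, direction turned for mesothelial 0.37 in nanopillar minus monolayer, endothelial -0.25 in nanopillar minus sandwich and basolateral efflux -0.084, fetal -0.46 and hypoxia -0.29 in monolayer minus fresh. Calls were lost for inflammatory -0.37 and pericentral 1.11 in nanopillar minus monolayer, YAP targets -0.21 and matrix -0.092 in nanopillar minus sandwich, glycolysis 0.45 and endothelial -1.28 in monolayer minus fresh, macrophage -0.76 and endothelial -1.24 in sandwich minus fresh and endothelial -1.16 in nanopillar minus fresh. Without the filter, with more genes tested, the counts were 24659 for monolayer, 18098 for sandwich and 16476 for nanopillar minus fresh, 12874 shared by the 3 cultures, 24201 for any difference among the 4 groups and 980 for nanopillar minus sandwich. There, direction turned for inflammatory 0.42 and cholangiocyte 0.03 in nanopillar minus monolayer, endothelial -0.01 in nanopillar minus sandwich and fetal -0.76 and hypoxia -0.22 in monolayer minus fresh, the call was lost for cholesterol -0.69 in monolayer minus fresh and gained for junctions -0.15 in nanopillar minus monolayer, cholangiocyte -0.005 in nanopillar minus sandwich and cholesterol 0.63 in sandwich minus fresh. With every probe tested on its own, direction turned for endothelial -0.022 in nanopillar minus sandwich, Nrf2 targets -0.01 in sandwich minus monolayer and hypoxia -0.011 in monolayer minus fresh, the call was lost for endothelial -2.30 in monolayer minus fresh and gained for junctions -0.21 in nanopillar minus monolayer, cholangiocyte -0.48 and stellate 0.26 in nanopillar minus sandwich, macrophage -1.34 in monolayer minus fresh and macrophage -1.03 in nanopillar minus fresh. The mean of a gene's probes turned hypoxia -0.047 in monolayer minus fresh and added cholangiocyte -0.43 and stellate 0.26 in nanopillar minus sandwich and fetal 2.93 in monolayer minus fresh. The deposited value table added cholangiocyte -0.43 in nanopillar minus sandwich. Slide as a block turned endothelial -0.099 in nanopillar minus sandwich and added cholangiocyte -0.41 in nanopillar minus sandwich.

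A fit of the 2 groups compared, with fewer arrays for the spread, gave 1099 genes for nanopillar minus sandwich, ended the calls of canalicular 0.76 and inflammatory -0.82 in nanopillar minus monolayer and added fetal 2.27 in monolayer minus fresh. A test against a fold of 1.5, which asks for larger changes by construction, passed 4945 genes for nanopillar minus monolayer, 108 for nanopillar minus sandwich, 3538 for sandwich minus monolayer, 8599 for monolayer, 5025 for sandwich and 4085 for nanopillar minus fresh, 3045 of them in all 3 cultures. Of the genes named that had passed, 10 of 33 no longer did in nanopillar minus sandwich, 1 of 20 in sandwich minus monolayer, 3 of 28 in sandwich and 2 of 27 in nanopillar minus fresh. Without the filter it was 3 of 33 in nanopillar minus sandwich. Rat as a block changed no list call, and neither it nor an intensity trend with robust spread moved a count by more than 1.5 times.

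The preset correlation decided most list calls. With the correlation estimated, the medians stay as they are and the tests allow for genes that move together. In nanopillar minus monolayer the lists that no longer passed were YAP targets -1.33, actin -1.58, bile acid 3.20, canalicular 0.76, cell cycle -0.68, cholesterol 1.83, phase I 2.24, mesenchymal transition -1.40, matrix -2.10, fat synthesis 2.05, fat oxidation 1.38, gluconeogenesis 2.73, plasma proteins 1.75, immediate early -0.92, inflammatory -0.82, transcription factors 1.29, respiratory chain 0.77, pericentral 1.16, periportal 1.39, phase II 2.33, uptake 1.41, unfolded protein 0.48, urea cycle 1.98, cholangiocyte -1.34 and mesothelial -1.72. In nanopillar minus sandwich they were YAP targets -0.48, actin -0.25, acute phase 0.57, bile acid 0.68, cholesterol 0.65, phase I 0.50, matrix -0.18, fat synthesis 0.67, fat oxidation -0.16, plasma proteins 0.54, Nrf2 targets 0.49 and phase II 0.46. For sandwich minus monolayer it was actin -1.34, bile acid 2.47, phase I 2.12, fat oxidation 1.36 and plasma proteins 1.16. Against fresh cells they were actin 2.96, cholesterol -0.82, phase I -3.99, plasma proteins -3.43, glycolysis 1.32, uptake -2.85, urea cycle -3.62 and endothelial -2.35 in monolayer. They were actin 1.30, cell cycle -1.18, clock -0.86, phase I -1.99, plasma proteins -2.32, pericentral -3.03, uptake -1.82, urea cycle -1.60, macrophage -1.10 and endothelial -2.15 in sandwich. In nanopillar cells they were actin 0.82, cell cycle -1.39, cholesterol 1.13, clock -0.99, phase I -1.55, plasma proteins -1.66, uptake -1.41, urea cycle -1.27 and endothelial -2.19. The pericentral list kept its call in monolayer (adjusted p = 0.0216) and nanopillar cells (adjusted p = 0.0485). Fry, which compares no list with other genes, passed further lists by its directional or its mixed test. These were erythroid 1.40 and junctions -0.15 in nanopillar minus monolayer and macrophage 0.22, cholangiocyte -0.43, stellate 0.16, endothelial 0.015 and lymphocyte 0.43 in nanopillar minus sandwich. They were Nrf2 targets 0.32 in sandwich minus monolayer, basolateral efflux 1.58, cell cycle -0.90, clock -0.41, fetal 2.27, hypoxia 0.21 and macrophage -1.34 in monolayer minus fresh, cholesterol 0.54 in sandwich minus fresh and macrophage -1.03 in nanopillar minus fresh.

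Leaving out 1 array or 1 rat changed calls or directions of the following results, with the range of their values. The nanopillar minus sandwich count ran from 120 to 2644. In that contrast matrix genes ran from -0.26 to -0.093, cholangiocyte markers from -0.47 to -0.17, stellate markers from 0.080 to 0.30, endothelial markers from -0.17 to 0.17, Alb from -0.063 to 0.34 and Hnf4a from -0.006 to 0.12. Junction genes in nanopillar minus monolayer ran from -0.23 to -0.053. In monolayer minus fresh it was -1.18 to -0.75 for cell cycle, -0.95 to -0.61 for cholesterol and -2.61 to -2.11 for endothelial markers. In sandwich minus fresh it was 0.45 to 0.77 for cholesterol, -1.26 to -0.79 for macrophage markers and -0.26 to 0.030 for Hnf4a. In nanopillar minus fresh it was -1.07 to -0.67 for macrophage markers, -0.068 to 0.024 for Abcb11 and -0.23 to 0.074 for Hnf4a. Fewer arrays give less power by construction, and with 1 rat left out each group has 2 arrays.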

Other observations

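The tests of the hepatocyte share, of a related Cyp2c transcript and of a shift between sex-dependent genes were chosen or revised only after the result was seen.

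Most urea cycle and amino acid catabolism genes were lower in culture than in fresh cells. In monolayer cells 56 of 57 were lower and 0 higher (0 higher and 57 lower adjusted over the list alone), median -3.62 [-3.50 and -3.97 on slides 2 and 3], adjusted p = 2.22e-18, adjusted p = 0.0586 with an estimated correlation. In sandwich cells 52 were lower and 2 higher, median -1.60 [-1.59, -1.50 and -1.71 on slides 1, 2 and 3], adjusted p = 3.92e-15, adjusted p = 0.0965 with an estimated correlation. In nanopillar cells 47 were lower and 0 higher (0 higher and 48 lower adjusted over the list alone), median -1.27 [-1.30 and -1.29 on slides 1 and 3], adjusted p = 2.02e-14, adjusted p = 0.0904 with an estimated correlation. Cps1, the first enzyme of the urea cycle, was 42.3-fold lower in monolayer, 1.92-fold in sandwich and 1.94-fold in nanopillar cells.

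Most sinusoidal uptake transporters, which bring bile acids, drugs and nutrients in from the blood, fell too. Of 22 measured, 20 were lower and 1 higher in monolayer cells, median -2.85 [-2.77 and -3.05 on slides 2 and 3], adjusted p = 1.21e-07, adjusted p = 0.0586 with an estimated correlation. In sandwich cells 18 were lower and 0 higher, median -1.82 [-1.71, -1.73 and -2.05 on slides 1, 2 and 3], adjusted p = 1.19e-07, adjusted p = 0.0965 with an estimated correlation. In nanopillar cells 18 were lower and 0 higher, median -1.41 [-1.38 and -1.48 on slides 1 and 3], adjusted p = 1.48e-07, adjusted p = 0.0904 with an estimated correlation. Slc10a1 was 1130-fold, 42.2-fold and 7.7-fold lower in monolayer, sandwich and nanopillar cells.

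The plasma protein list was higher in nanopillar than in sandwich cells by a median of 0.54, a call lost with an estimated correlation (adjusted p = 0.19). A slide effect as the whole cause is argued against by 0.532 with slide as a block and by 0.491 and 0.601 on slides 1 and 3. A lower share of hepatocytes in the sandwich cultures stays undecided. Of 3 marker lists of other cells, 0 had a median above 0 by more than its SE across genes (not independent replicates). Stellate gave 0.158 (SE 0.329), macrophage 0.223 (0.231) and endothelial 0.015 (0.176), negative under several settings. Vim (3.45-fold) and Timp2 (5.09-fold), which other liver cells also make, were lower in nanopillar cells, and cholangiocyte markers had a median of -0.43. No test separated surface, overlay and medium, of which the labels give only the culture type.

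Cyp2c12, a gene higher in female than in male rat liver, was higher in nanopillar than in sandwich cells by 7.31 (3.50 with a normexp background to 8.10 without sandwich 1), with 1 of 3 sandwich arrays above background and a nanopillar SD of 1.5. The call was lost without rat 2 (adjusted p = 0.0533). A related transcript read by the probe stays undecided, as Cyp2c12 was dim in sandwich cells. Cyp2c7 gave 2.804, the largest of the other Cyp2c genes measured (2.23 against 3.50 with normexp). Transcripts without a probe stay open. A shift from genes predominant in males to those predominant in females stays undecided: the other 8 female-predominant genes had a median of 1.055 and 10 male-predominant genes one of 0.443. The difference of 0.612 had a two-sided exact permutation p = 0.261 across genes, which are not independent replicates.

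Mt1 and Slc30a2, both known to respond to zinc, were higher in nanopillar than in sandwich cells by 4.52 and 3.35. More available zinc was predicted to raise the exporter Slc30a1 and lower the importer Slc39a10. Slc30a1 gave 1.148 (adjusted p = 0.000853, 3 of 3 arrays beyond those of the other group) and Slc39a10 was at least 1.9-fold lower (adjusted p = 0.0277), so zinc is a candidate explanation found and tested on the same data. Stronger glucocorticoid action, which also raises metallothionein, stays undecided (median 0.347, SE across genes 0.274, 12 responsive genes, 3 higher and 2 lower). The acute phase and interleukin-6 list, which holds Mt1 (median 0.57), and the Nrf2 target list (0.49) were higher too. Camera gave adjusted p = 5.09e-08 and 1.49e-07, each 0.19 with an estimated correlation. Signals of both lists also raise metallothionein and stay open beside zinc, and the labels give no media.

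In fits of 6 arrays the real grouping gave 11816 genes for nanopillar minus monolayer, 1099 for nanopillar minus sandwich, 10326 for sandwich minus monolayer, 14171 for monolayer minus fresh, 11093 for sandwich minus fresh and 9495 for nanopillar minus fresh, and the highest of the other splits gave 0 each time. With 1 of 10 splits being the real one, the splits are too few for a share under 0.05. For any difference among the 4 groups, 1 of 100 splits of the 12 arrays, the real one, gave as many as 15781 genes. This argues against chance as the source of that count. The other splits were drawn without regard to rat or slide, and they do not bear on the 6 contrasts between 2 groups. The highest other split gave 7060.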
